A study of Homo sapiens with 2 samples.

How the data were processed

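Poly(A) RNA of HuH6 hepatoblastoma cells, unedited (HuH6_WT) or with a CRISPR/Cas9 knockout of PIM3 (PIM3_KO), was sequenced in 1 library per group. Per the labels' protocols, total RNA was purified on RNeasy columns, passed through 2 rounds of poly(A) selection, made into directional libraries with a NEBNext Ultra kit and read on a NextSeq500 as single-end 75 bp reads. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.7.3a, Cufflinks 2.2.1 and the build GRCh38. The annotation release, the strand setting and the filters are not given in the sources used here.

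The authors deposited FPKM values, fragments per kilobase of transcript scaled to library size, in 1 column per library, as named in the table's header. The table had 62571 rows. Of these, 1736 joined several gene symbols into 1 locus, and 2375 symbols occurred in more than 1 row. Reads of a symbol with copies on alternate sequences can be split or lost, as seen for RPL7A and RPS18, so only the 53139 symbols with 1 row of their own were used; this choice was made after the table was examined. Joined loci were left out of all counts except where named. Antisense partners cannot be excluded as a source of reads where the strand setting is unknown.

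Read depth was looked for in the low values. For genes with 1 exon and 1 transcript of 600 to 5000 bp, FPKM multiplied by kilobases (length less 200 bp) came in steps of 0.0353 in HuH6_WT and 0.0450 in PIM3_KO. Of such genes with under 20 reads, 96.7% and 96.5% lay within 0.05 of a whole number of reads. The steps imply normalisation totals of 28.3 M and 22.2 M reads, which need not equal the mapped reads. Read estimates for genes with several exons or transcripts are approximate and no count test was run. Transcript lengths, positions and GC content came from GENCODE release 29 on GRCh38, of which 11068 of the 11253 genes tested had a match. Length and GC content were those of 1 transcript per gene. For coding genes this was the longest one marked as principal in the annotation, where there was one, and otherwise the longest. It need not be the transcript expressed, so all values that use length are approximate.

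The statistic was the log2 ratio of FPKM + 1 in PIM3_KO over HuH6_WT, which understates differences of low genes. Genes with a mean of at least 1 FPKM over both libraries were counted when they differed at least 2-fold. With 1 library per group, no test between conditions is possible, and random lists describe these libraries alone. For 37 gene lists, the median of the members with a mean of at least 1 FPKM was set against 10000 random lists of the same size matched on mean level in 20 bins; lists with under 4 such members were not ranked. A percentile below 2.5 or above 97.5 was called standing apart. Lists, thresholds and the rule for genes to name were fixed before the data were examined.

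The rule named the 12 genes with the highest and the 12 with the lowest ratios among named genes with at least 5 FPKM in 1 library, leaving out mitochondrially encoded, small nuclear, small nucleolar, ribosomal RNA, microRNA, XIST and Y-linked genes. It added the PIM kinases, for each list the members with the 2 highest and 2 lowest ratios, and POU5F1, SOX2, NANOG and MYC. Clone names were not counted as named genes, and some genes that the rule takes are not reported here. Chosen after their values were seen were ALB, C3, FGA, FGG, HNF4A, GPC3, BMP4, GLUL, LEF1, LGR5, NOTUM, SP5, ZNRF3, CDKN1A, TP53INP1, JUN, ANXA1, VIM, F2, F12, KDM5A, KDM5C, LAMC3, MRPL54, NDUFB7, NDUFS7, PLXNA1, PLXNB1 and the joined loci.

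Settings also tried, chosen before the data were seen, were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, rescaling each library to the same total (TPM) and centring the ratios on their median. Chosen after seeing the data were a lowess correction for transcript length (fraction 0.3), random lists matched on level and length in 10 bins each, and a further correction for the median of chromosomal bins of about 40 coding genes. The percentile of each chromosome used 2000 length-matched lists. The code was tested on simulated data with the real levels and lengths of about 10740 genes, a gene-to-gene spread of 0.3 and a slope of -0.2 per doubling of length. Of 200 changed genes, those at a mean of at least 5 FPKM passed the 2-fold threshold in 94.7% of cases at 3-fold and 100% at 6-fold, against 0.456% of unchanged genes. The spread of 0.3 was assumed, while the real log2 ratios had an SD of 0.715. With 1 library per group the spread of unchanged genes is unknown, so these rates do not give the share of false calls in the real data. Of 200 unchanged lists 6% stood outside with length matching, and of 100 unchanged lists of short transcripts 98% did when matched on level alone and 6% when matched on length too. These shares rest on the same assumed spread and on genes that vary independently, so they need not hold for the real lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.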

Results

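RNA was sequenced from HuH6 cells, an established human line from hepatoblastoma, the embryonal liver tumour of childhood. One group held the parental cells (HuH6_WT), and the other held HuH6 cells in which the PIM3 gene had been disrupted with CRISPR/Cas9 (PIM3_KO). PIM3 encodes a serine/threonine kinase that promotes cell survival and growth. The series asked how loss of this kinase bears on tumour formation and stemness. Each group had 1 library, so no difference given here has a replicate check and no p-value was computed. Other differences between the edited and the parental cells cannot be told apart from effects of PIM3 loss. The value of 1 read implied normalisation totals of 28.3 M reads for HuH6_WT and 22.2 M reads for PIM3_KO. On a 2 kb transcript 3 reads then amounted to 0.0588 and 0.0750 FPKM.

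PIM3 was lower in the library labelled as its knockout. The gene (ENSG00000198355.4) lies on chromosome 22 from position 49960513 to 49964080 of GRCh38 and measured 34.2 FPKM in HuH6_WT and 14.0 FPKM in PIM3_KO, a log2 ratio of -1.23. The knockout value was 41.1% of the parental one, with an exact 95% interval of 37.6% to 44.8% from about 2104 and 677 estimated reads, which covers counting error only. The related kinase PIM1 measured 80.0 and 60.5 FPKM, and PIM2 measured 6.82 and 9.09 FPKM. The log2 ratio of PIM2 was 0.37, and -0.04 after rescaling both libraries to the same total (TPM). A small insertion or deletion left by Cas9 can spare the transcript, so the remaining PIM3 level shows neither presence nor absence of the protein. Genes beside PIM3 on 22q were lower in the same library, with values given further on.

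Single genes differed by large factors in both directions. AFP, the fetal albumin-like protein used as a marker of hepatoblastoma, measured 1.19 FPKM in HuH6_WT and 70.1 FPKM in PIM3_KO, a 59.0-fold ratio. MMP1, an interstitial collagenase, measured 0.616 and 49.4 FPKM, PLAC8 6.04 and 141 FPKM, and the transcription factor gene BATF3 3.47 and 65.7 FPKM. In the other direction, the membrane progestin receptor gene PAQR5 measured 95.1 and 1.04 FPKM, and ACTA2, the smooth muscle actin, 87.4 and 10.5 FPKM. COL26A1, a collagen, measured 9.92 and 0.0809 FPKM, GAD1, which makes the transmitter GABA, 42.1 and 6.74 FPKM, and PLOD2, a collagen lysyl hydroxylase, 13.9 and 1.78 FPKM.

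Among 11253 genes with a mean of at least 1 FPKM, 775 were at least 2-fold higher and 516 at least 2-fold lower in PIM3_KO. The higher genes made up 60.0% of these. At a 4-fold threshold the counts were 104 and 59, and among 9691 protein-coding genes the 2-fold counts were 540 and 422. The 12 genes with the highest ratios also included CEP97 (0.904 and 69.0 FPKM), a centrosomal protein gene, LINC01405, the hyaluronan-binding protease HABP2 (0.455 and 13.2 FPKM), GNRH2 and GLYATL1. The remaining 3 were RNY1P9, RNY1P16 and ATP5F1EP2, short pseudogenes listed at 0 in HuH6_WT. The 12 lowest also included GPX1 (41.5 and 0.322 FPKM), a glutathione peroxidase, LINC00674, the lysosomal GTPase RRAGD (11.0 and 0.721 FPKM), the G protein subunit GNAI1 (15.4 and 1.39 FPKM), PCSK1N and SAMD5. The last of them, the pseudogene TAF9P3, was listed at 0 in PIM3_KO. GPX1 is annotated as a polymorphic pseudogene, and PAQR5, SAMD5, GLYATL1, RNY1P9 and RNY1P16 overlap another gene on the same strand, so these values are less certain. ACTA2 and FAS overlap on opposite strands, and the strand setting of the counting is not known. Of the genes past 2-fold, 61 higher and 36 lower ones were listed at 0 in 1 library, and 78 of these 97 had transcripts under 300 bp. The FPKM totals were 787250 and 1086210, a log2 ratio of -0.46 for HuH6_WT over PIM3_KO. Rescaling to TPM moved the median log2 ratio from 0.01 to -0.40. Ratios of low genes moved less, such as LIN28B from 2.08 to 1.99. Under TPM 323 genes were at least 2-fold higher and 1622 at least 2-fold lower, and the higher share became 16.6%. Gene groups are therefore given relative to random lists, which a common shift hardly touches.

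**Figure D1:**
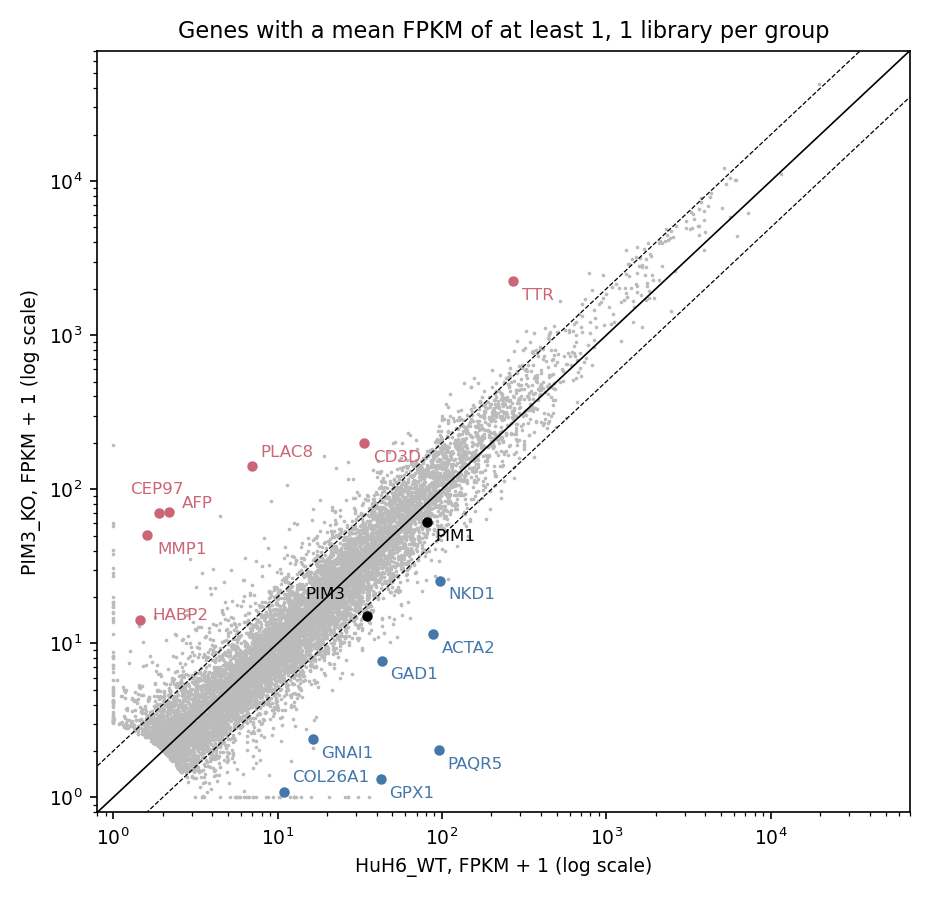
FPKM + 1 of each gene with a mean FPKM of at least 1 in HuH6_WT (horizontal, log scale) and PIM3_KO (vertical, log scale), with the line of equal values and dashed lines at 2-fold on this scale. Red names are higher in the knockout library, such as AFP at 1.19 and 70.1 FPKM, blue names are lower, such as PAQR5 at 95.1 and 1.04 FPKM, and PIM kinases are black.

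Secreted proteins of the mature hepatocyte were the group that stood highest in the knockout library. Of 18 measured members, 15 were higher, 12 of them at least 2-fold, and none was at least 2-fold lower. TTR, the thyroxine and retinol carrier transthyretin, measured 270 and 2232 FPKM, its partner RBP4 0.805 and 13.8 FPKM, ALB 0.520 and 9.18 FPKM, and complement C3 12.2 and 58.4 FPKM. The fibrinogen chains FGA, FGB and FGG had log2 ratios of 1.81, 1.95 and 1.22, while the hyaluronan-binding ITIH2 measured 20.3 and 11.0 FPKM and ITIH3 2.53 and 1.67 FPKM. The list's median log2 ratio was 1.36, above the 10000 random lists matched on level (percentile 100), and it stood above with lists matched on transcript length too. Enzymes of hepatocyte metabolism did not stand apart as a group (7 measured, percentile 57.6): the bile acid enzyme CYP27A1 measured 12.9 and 41.3 FPKM and FBP1 0.242 and 2.16 FPKM, but ASS1 83.3 and 68.5 FPKM. Hepatocyte transcription factors lay within the random range (10 measured, percentile 33.1), with HNF4A at 36.1 and 32.7 FPKM, CEBPB at 87.1 and 103 FPKM, PROX1 at 4.40 and 1.99 FPKM and FOXA2 at 126 and 172 FPKM.

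Targets of WNT/beta-catenin signalling, the pathway most often mutated in hepatoblastoma, stood lowest. Of 16 measured members, 13 were lower in PIM3_KO and 7 were at least 2-fold lower, and 0 were at least 2-fold higher. The feedback inhibitor NKD1 measured 96.7 and 24.6 FPKM, APCDD1 49.6 and 12.3 FPKM, NOTUM 42.1 and 13.4 FPKM, LEF1 3.08 and 0.552 FPKM and SP5 362 and 161 FPKM. ZNRF3 and BMP4 each had a log2 ratio of -1.25. DKK4 (2.03 and 4.98 FPKM), FGF19 (0.652 and 1.47 FPKM) and MYC (94.8 and 136 FPKM) were the members higher in the knockout library, and GLUL and LGR5 lay near equality at -0.13 and -0.19. The median log2 ratio was -0.79, at percentile 0 of the random lists, with or without matching on transcript length.

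**Figure D2:**
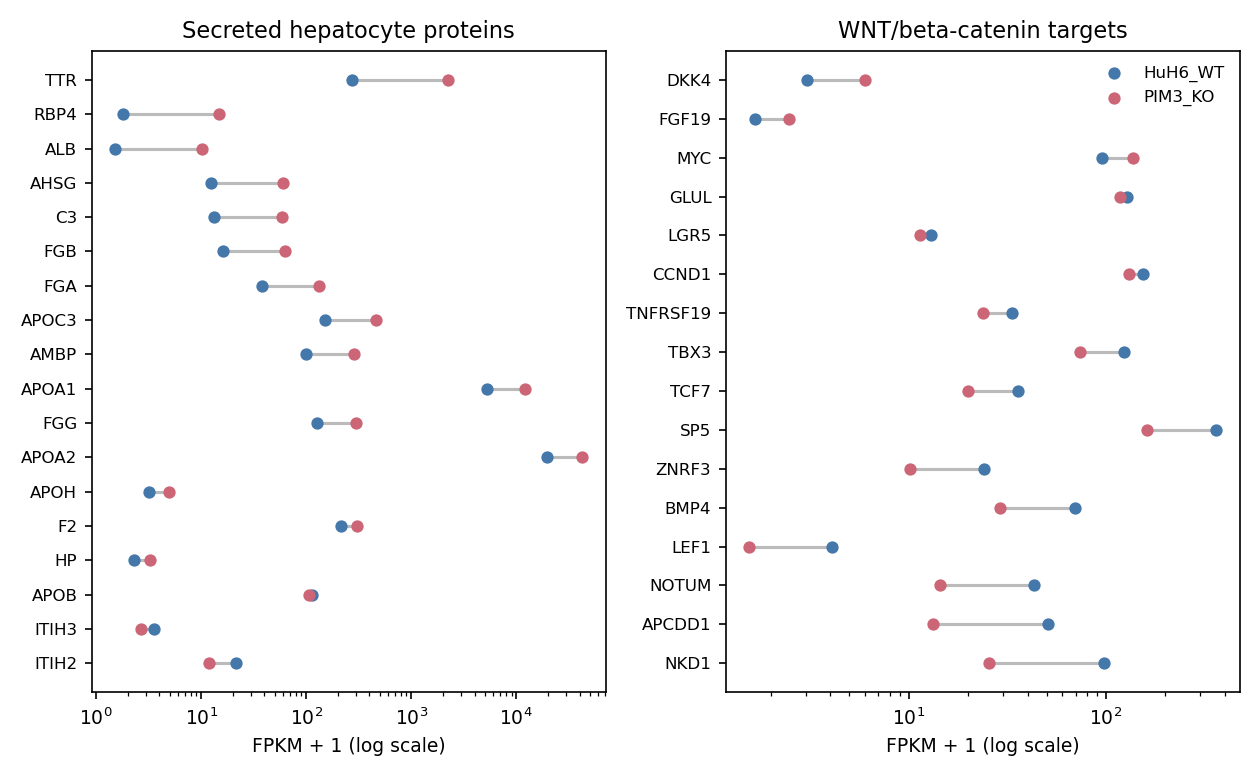
FPKM + 1 (log scale) of each measured gene of the secreted hepatocyte protein list (left, 18 genes) and the WNT/beta-catenin target list (right, 16 genes) in HuH6_WT (blue) and PIM3_KO (red), ordered by ratio. On the left 15 of 18 genes are higher in PIM3_KO, and on the right 13 of 16 are lower.

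The lists of p53 targets, immediate early genes, NRF2 targets and migration genes also stood below. The CDK inhibitor and p53 target list had a median of -0.50 (21 measured, 15 lower, percentile 0.01). The death receptor FAS measured 8.45 and 2.81 FPKM, the repair factor XPC 24.9 and 9.79 FPKM and TP53INP1 7.94 and 2.92 FPKM, while CDKN1A was near equality at 128 and 118 FPKM and CDKN2C measured 0.842 and 2.49 FPKM. Immediate early and ERK feedback genes had a median of -0.44 (17 measured, 12 lower, percentile 0.03), with DUSP6 at 194 and 73.7 FPKM, EGR2 at 35.2 and 13.8 FPKM and JUN at 139 and 56.9 FPKM, against ETV4 at 62.8 and 94.6 FPKM. NRF2 targets had a median of -0.40 (17 measured, 11 lower, percentile 0.14). The aldo-keto reductases AKR1C1 and AKR1C2, near-identical genes whose reads can be split wrongly, measured 11.0 and 2.87 FPKM and 29.7 and 9.45 FPKM, and the quinone reductase NQO1 went the other way at 3.17 and 21.8 FPKM. Migration, matrix and EMT genes had a median of -0.29 (18 measured, 11 lower, percentile 1.15), with the integrin ITGB1 at 122 and 42.1 FPKM, MMP2 at 14.5 and 4.73 FPKM and ANXA1 at 16.9 and 6.93 FPKM, while VIM measured 25.1 and 47.0 FPKM. This last list did not stand apart when matched on transcript length (percentile 3.52). It stood below again after the correction for both length and chromosomal bins (percentile 0.18). With that correction, the distance from random lists was -0.33 instead of -0.64 for immediate early genes and -0.24 instead of -0.53 for NRF2 targets (percentiles 0.475 and 2.06). Length matching alone gave distances of -0.53 and -0.51. The corrected distance was -0.44 instead of -0.66 for p53 targets and -0.70 instead of -0.92 for WNT/beta-catenin targets. Secreted hepatocyte proteins had 0.82 instead of 1.16.

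Pluripotency and stemness genes did not stand apart as a group, and members differed in direction. The reprogramming factor KLF4 measured 48.3 and 22.1 FPKM and LIN28A 316 and 196 FPKM, whereas LIN28B was listed at 0 in HuH6_WT and measured 3.23 FPKM in PIM3_KO. Of 11 measured genes, 7 had positive ratios, and the median of 0.36, or -0.09 under TPM, lay at percentile 81.3. SOX2 (0.0609 FPKM and listed at 0) was near the floor, where 3 reads amount to 0.0458 and 0.0583 FPKM. NANOG measured 0.111 and 0.141 FPKM, about 15.6 and 15.7 estimated reads. POU5F1 was listed at 0 in each of its 7 rows, as were the ribosomal protein genes RPL7A and RPS18, so its value says nothing of its expression. Fetal liver and hepatoblast genes lay within the random range (11 measured, 7 with positive and 4 with negative ratios, median 0.38, or -0.09 under TPM, percentile 78.7) despite AFP. GPC3, a surface proteoglycan of hepatoblastoma, measured 694 and 607 FPKM, IGF2BP3 27.5 and 22.8 FPKM and CD24 79.0 and 61.1 FPKM. Imprinted genes (4 measured, percentile 57.3) included PEG10 at 128 and 198 FPKM and PLAGL1 at 10.4 and 5.67 FPKM.

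Neither list of proliferation genes stood apart from random lists of like level. Among G2/M and mitosis genes 16 of 22 had positive ratios (median 0.39, or -0.07 under TPM, percentile 94.1), led by the topoisomerase TOP2A at 102 and 285 FPKM and CDCA3 at 43.5 and 96.1 FPKM, with HMMR at 28.7 and 17.0 FPKM. This list stood above when random lists were matched on transcript length (percentile 98.2) and after the further correction for chromosomal bins (99.2). Among G1/S and DNA replication genes 12 of 22 were lower (median -0.07, percentile 4.51), led by the helicase subunits MCM2 at 82.6 and 39.0 FPKM and MCM5 at 133 and 67.6 FPKM, with CCNE1 at 22.9 and 37.7 FPKM. MYC targets and ribosome biogenesis genes lay within the random range (21 measured, percentile 41.3), with NOP56 at 257 and 613 FPKM and POLR1B at 18.7 and 14.7 FPKM. BCL2 family and apoptosis genes did too (19 measured, percentile 49.2), with CASP8 at 13.2 and 5.21 FPKM and BAD at 34.5 and 83.9 FPKM.

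Most genes of the ribosome and of oxidative phosphorylation had positive ratios. Cytosolic ribosomal protein genes had a median of 0.76 (0.30 under TPM), with 31 of 32 positive ratios, RPL27A at 1703 and 3619 FPKM and RPL14 at 7314 and 6165 FPKM, and nuclear genes of oxidative phosphorylation 0.64 (0.17 under TPM), with 20 of 22, COX4I1 at 814 and 1956 FPKM and UQCRC2 at 110 and 83.1 FPKM. Neither list stood apart from others of like level (percentiles 97.4 and 89.2), but the ribosomal one did with a pseudocount of 5 (97.6). The ratio was lower the longer the transcript: the 969 coding genes with the shortest transcripts, 294 to 1338 bp, had a median log2 ratio of 0.58 and the 968 with the longest one of -0.25. Log2 transcript length accounted for 12.8% of the variance of the ratios across coding genes. These are lengths of 1 annotated transcript per gene, which need not be the one expressed. Mitochondrially encoded MT-CYB measured 649 and 999 FPKM, and MT-ND6 6.54 and 7.23 FPKM.

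Most of the other stress and metabolic lists lay within the random range. NF-kB and inflammatory genes stood just above (10 measured, median 0.42, percentile 97.7), with LCN2 at 0.620 and 3.36 FPKM, CCL20 at 4.41 and 12.6 FPKM and TNFAIP3 at 18.5 and 8.24 FPKM. They did not with length-matched lists (percentile 96.3, distance 0.38 instead of 0.42) or after the further correction for chromosomal bins (83.9, distance 0.17). Metallothioneins lay within the range on level (6 measured, percentile 8.10) but below length-matched lists (percentile 0.11), with 3 members positive and 3 negative, MT1M at 0.180 and 2.29 FPKM and MT2A at 259 and 194 FPKM. Lists within the random range were the integrated stress response (percentile 39.6, median 0.21, or -0.25 under TPM, with TRIB3 at 40.7 and 69.9 FPKM but ATF3 at 229 and 87.0 FPKM), the unfolded protein response (73.1, but 97.7 and above after the correction for chromosomal bins, CALR at 370 and 799 FPKM), heat shock (12.2, CRYAB at 2.23 and 3.92 FPKM but HSPB1 at 280 and 247 FPKM), interferon response (82.6, BST2 at 156 and 340 FPKM), JAK-STAT targets (10.4, IL6ST at 42.9 and 18.8 FPKM), cholesterol synthesis (3.56, SREBF2 at 78.4 and 35.9 FPKM), glycolysis and hypoxia (50.2, median 0.17, or -0.30 under TPM, with CA9 at 1.51 and 5.15 FPKM but PKM at 434 and 248 FPKM), replication-dependent histones (91.3) and housekeeping genes (14.6). Positive ratios were held by 5 of 13 JAK-STAT targets, such as FGB at 15.3 and 62.1 FPKM. So they were by 8 of 18 cholesterol synthesis genes, such as FDPS at 317 and 591 FPKM. Negative ratios were held by 3 of 14 unfolded protein response genes and 2 of 5 interferon response genes. Of 33 lists with at least 4 measured members, 3 stood above and 6 below, the latter including the list of genes beyond PIM3. Chance would put 1.65 outside only if random lists matched on level alone described unchanged lists. In the simulation they did not for unchanged lists of short transcripts, of which 98% stood outside, against 6% when matched on length too. Simulated genes varied independently with an assumed spread of 0.3, so neither share need hold for the real lists. With length-matched lists, 2 stood above and 6 below.

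**Figure D3:**
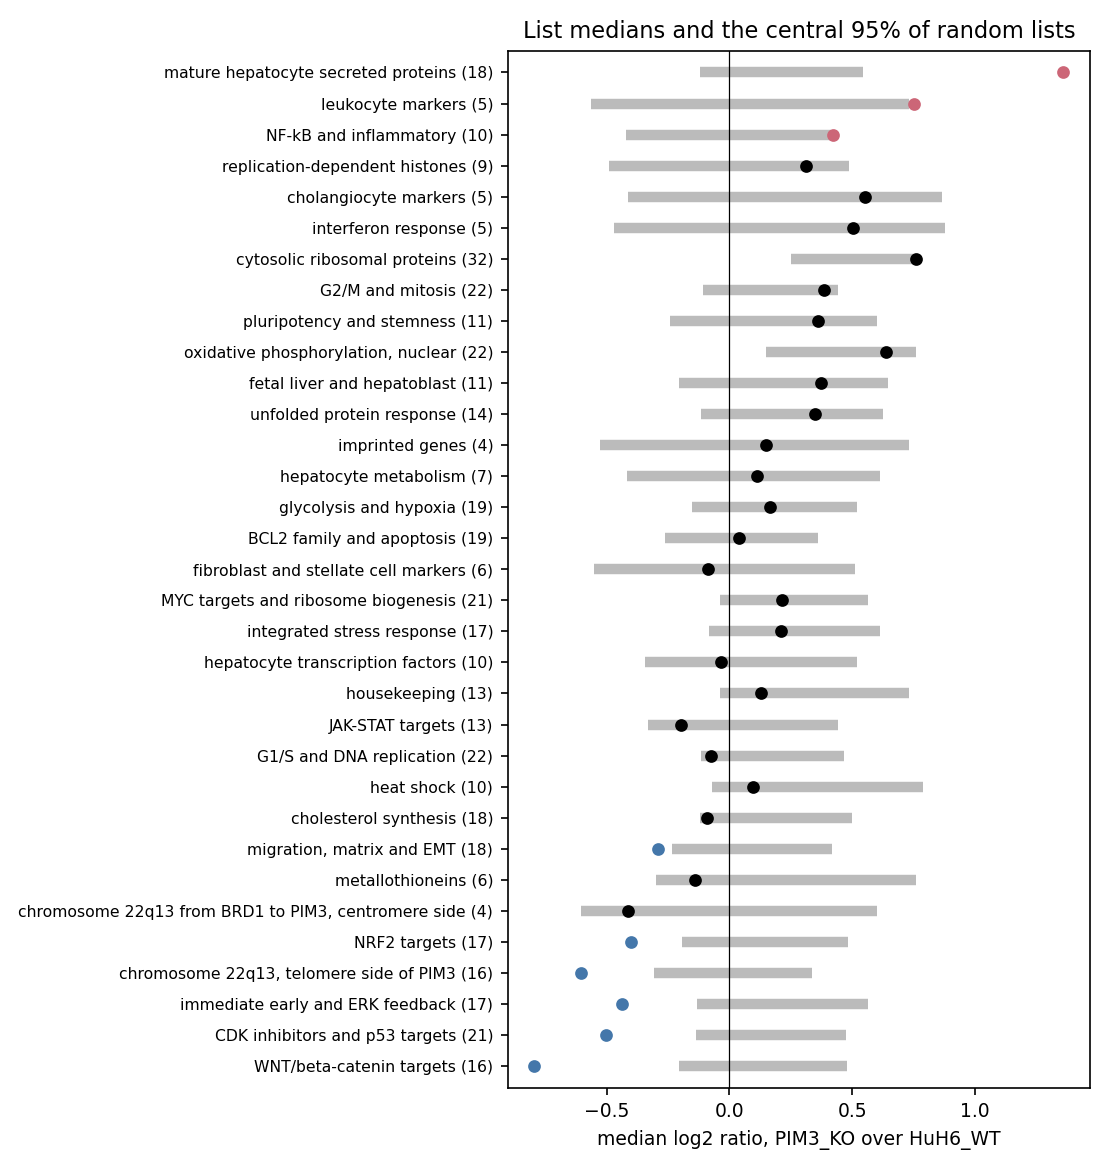
Median log2 ratio of PIM3_KO over HuH6_WT (points) for each of 33 gene lists, with the number of measured genes in parentheses and grey bars for the central 95% of 10000 random lists of like expression level. Red points stand above the bar (3 lists, with secreted hepatocyte proteins at 1.36), blue points below it (6 lists, with WNT/beta-catenin targets at -0.79), and black points within.

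Of 16 neuroblastoma markers 15 were under 1 FPKM in both libraries, as were 7 of 11 endothelial, 7 of 14 fibroblast and stellate cell, 6 of 12 leukocyte and 5 of 10 cholangiocyte markers. Some of the rest were abundant in both, with the tight junction gene CLDN4 at 217 and 166 FPKM and LAPTM5 at 72.3 and 63.9 FPKM. The T cell receptor chain CD3D measured 32.7 and 198 FPKM and EGFL7 15.4 and 45.6 FPKM, CFTR measured 0.0559 and 4.75 FPKM, and TIE1 11.8 and 6.02 FPKM. The leukocyte list stood above on 5 measured genes (median 0.75, percentile 97.8), though not with length-matched lists (95.3). The fibroblast and cholangiocyte lists lay within the random range (percentiles 44.8 and 83.0).

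Genes at the end of chromosome 22q were lower on both sides of PIM3. Of 16 measured genes between PIM3 and the telomere, 14 were lower in PIM3_KO, with a median log2 ratio of -0.61 (percentile 0.02). The correction for chromosomal bins, which removes a regional shift by construction, left a distance of -0.22 (percentile 5.46). The semaphorin receptor PLXNB2 measured 89.6 and 26.4 FPKM and SBF1 had a log2 ratio of -1.26, against NCAPH2 at 78.6 and 84.7 FPKM and SYCE3 at a log2 ratio of 0.79. The list from BRD1 to PIM3 held 4 genes with a median of -0.42 (percentile 8.49), of which ZBED4 measured 5.34 and 3.19 FPKM and CRELD2 24.7 and 35.4 FPKM. The 16 coding genes nearest to PIM3 on the centromere side, from position 45413691, had a median of -0.42 and the 188 before them one of -0.02. Whole chromosomes also differed: against length-matched lists, 5 of 23 stood below and 7 above. The median of chromosome 3 lay -0.25 from such lists and that of chromosome 19 lay 0.23 above them.

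**Figure D4:**
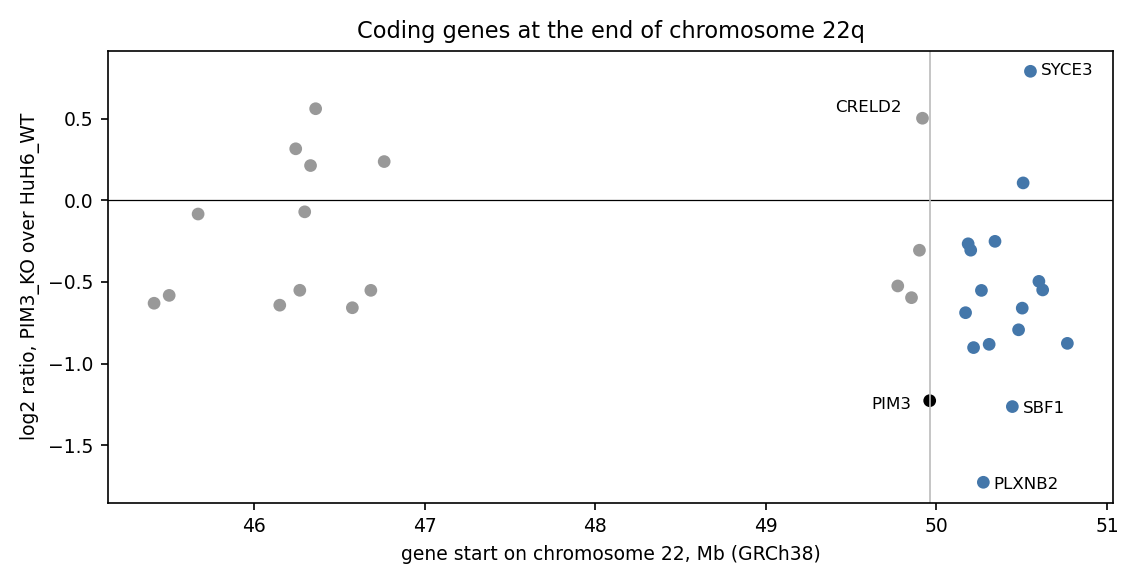
Log2 ratio of PIM3_KO over HuH6_WT (vertical) for coding genes at the end of chromosome 22q by their start position in Mb on GRCh38 (horizontal), with PIM3 in black at the grey line, the 16 genes nearest to it on the centromere side in grey and the 16 beyond it in blue. The medians are -0.42 and -0.61.

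**Figure D5:**
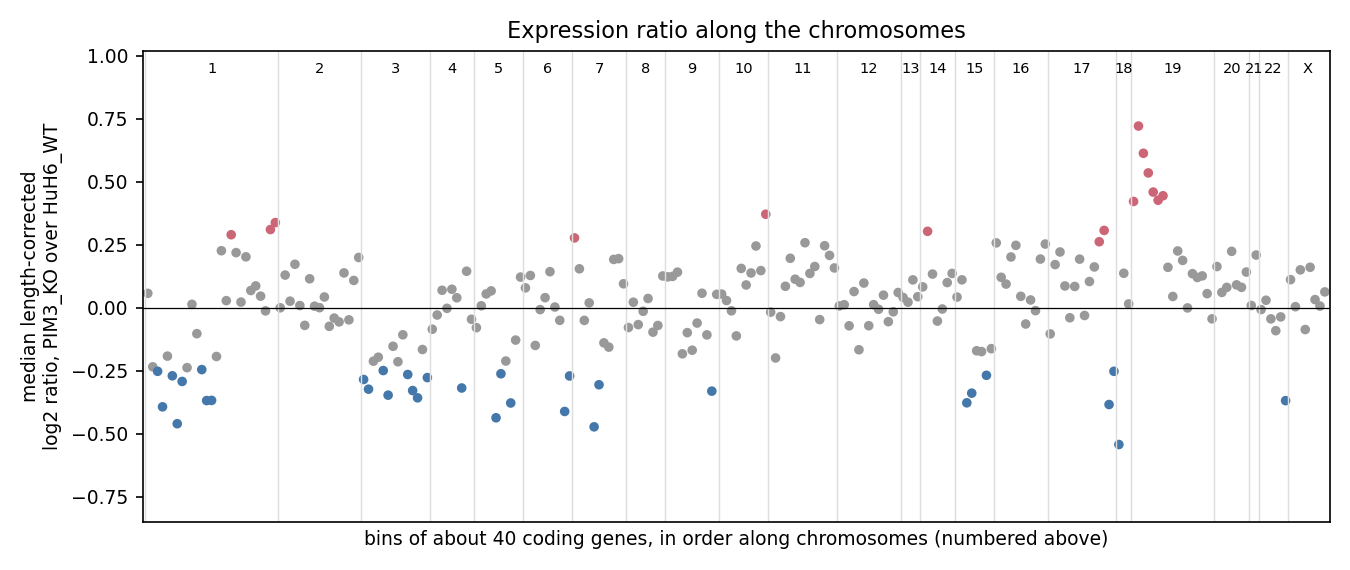
Median log2 ratio of PIM3_KO over HuH6_WT, corrected for transcript length, in 241 bins of about 40 coding genes along the chromosomes numbered above. Bins outside the central 99% of random bins are blue (32 lower) or red (15 higher), and 7 neighbouring bins of chromosome 19 stand highest, at a median of 0.50.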

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

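The alternatives that use transcript length or chromosomal bins were chosen after the data were seen. With 1 library per group, no library could be left out and no other split of the samples exists for comparison. None of the named genes, lists and families reversed its direction from a called value under the alternatives run on them. A pseudocount of 0.1 gave 1031 genes at least 2-fold higher and 812 at least 2-fold lower, and one of 5 gave 399 higher and 172 lower genes and a PIM3 log2 ratio of -1.04; a larger pseudocount shrinks the ratios of low genes by construction. Rescaling to TPM gave 323 higher and 1622 lower genes and -1.67 for PIM3, since the FPKM totals differ (log2 ratio -0.46 for HuH6_WT over PIM3_KO). It moved the median log2 ratio from 0.01 to -0.40, and the ratios of low genes less. The number of lists standing above became 1 with a mean of at least 5 FPKM and 1 after the length correction, secreted hepatocyte proteins in both cases, while 7 stood below in each; the cause was not tested. The genes beyond PIM3 on 22q lay -0.22 from random lists (percentile 5.46) after the correction for chromosomal bins, which removes a regional shift by construction. Apart from the genes beyond PIM3, which lost their call after that correction, lists were recomputed in 252 cases, of which 235 kept their call, 9 lost it and 8 gained one; for named genes 717 of 797 ratios kept their side of the 2-fold threshold, 51 lost it and 29 gained it. For gene families 170 of 199 calls were kept, 26 were lost and 3 gained. The lists of WNT/beta-catenin targets, p53 targets, immediate early genes, NRF2 targets and secreted hepatocyte proteins stood apart under all 8 alternatives run on them. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor, where 3 reads on a 2 kb transcript amount to 0.0588 FPKM in HuH6_WT and 0.0750 in PIM3_KO.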

Other observations

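Apart from the list of genes beyond PIM3, fixed beforehand, the tests and the gene families in this part were chosen after the result was seen. Of 25 families taken by gene symbol, the subunits of mitochondrial complex I had positive ratios in 24 of 24 measured, 8 of them at least 2-fold, with NDUFS7 at 46.3 and 174 FPKM and NDUFB7 at 148 and 459 FPKM. Their median log2 ratio was 0.85 (0.39 under TPM) at percentile 99.98, but 96.7 with length-matched lists and 97.2 after the correction for chromosomal bins. Mitochondrial ribosomal protein genes followed (55 of 60 positive, median 0.56, or 0.10 under TPM, percentile 99.96, but 94.5 length-matched and 96.7 after the bin correction), with MRPL54 at 28.4 and 87.0 FPKM. Complement components had positive ratios in 5 of 5 (median 0.99, or 0.65 under TPM, percentile 99.3 length-matched and 99.1 after the bin correction). Coagulation factors had them in 5 of 6 (median 0.59, or 0.14 under TPM, percentile 98.7 length-matched, but 96.7 and within the range after the correction for chromosomal bins), such as F12 at 9.09 and 18.9 FPKM. C3 and F2 are also in the secreted hepatocyte list.

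Of the families below random lists of like level, 5 in all, none stood apart once matched on length. Integrins (median -0.39, percentile 2.39, and 10.4 length-matched) and tRNA synthetases (median -0.11, percentile 1.54, and 5.27 length-matched) were among them. Laminins, the chains of basement membranes, had a median of -0.47 (7 of 9 lower, percentile 0.23, but 2.74 length-matched and 15.5 after the bin correction), with LAMC3 at 3.22 and 1.48 FPKM against LAMB3 at 10.7 and 21.3 FPKM. Semaphorins and plexins, guidance cues and their receptors, had a median of -0.41 (12 of 17 lower, percentile 0.88, 4.94 length-matched and 0.825 after the bin correction), with PLXNA1 at 19.1 and 8.61 FPKM and PLXNB1 at 59.9 and 28.8 FPKM. Histone demethylases had a median of -0.47 (10 of 14 lower, percentile 0.66, 9.76 length-matched and 0.53 after the bin correction), with KDM5C at 22.7 and 9.51 FPKM against KDM5A at 20.1 and 52.8 FPKM. Among joined loci, the one of APOC1 and APOE measured 5442 and 9831 FPKM, the one of SRPRB and TF (transferrin) 322 and 769 FPKM. Of WNT targets in joined loci, the one of AXIN2 and CEP112 measured 51.1 and 33.0 FPKM and the one of RNF43 and SUPT4H1 237 and 292 FPKM. IGF2 and H19, imprinted growth genes, lie in joined loci listed at or near 0 in both libraries. H19 occurred in more than 1 such row, where reads can be split or lost, so its value says nothing of its expression. The IGF2 locus measured 0.0961 FPKM in HuH6_WT and was listed at 0 in PIM3_KO. Whether reads were lost there was not tested.

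Short transcripts were higher and long transcripts lower in PIM3_KO, with a slope of -0.24 log2 units per doubling of length over 9689 coding genes. Abundant short mRNAs of a few groups do not carry it: without ribosomal, oxidative phosphorylation and secreted protein genes the slope was -0.23 (95% bootstrap interval -0.24 to -0.21). The fragment length in the FPKM formula falls short as well. With the same 200 bp subtracted, 96.7% of the low single-exon genes in HuH6_WT and 96.5% in PIM3_KO came in whole reads. The formula thus took a like length in both libraries. Transcripts of at least 2 kb gave -0.15, while even fragments of 400 bp in one library and 50 bp in the other would give -0.09. The slope was negative in each of 5 expression classes. It was weakest, at -0.15, in the lowest class, where the 1 FPKM added before the log shrinks ratios by construction. RNA integrity or size selection may have differed between the libraries. This cannot be told apart from an effect of the knockout, which was not tested, because 1 library per group leaves RNA quality and biology mixed.

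Neighbouring genes were shifted together along chromosomes. Length and GC trends do not account for this, since the SD of the 241 bin medians stayed at 0.193 after both corrections against at most 0.112 in 1000 shuffles of gene order. A correlation of 0.448 between bins 3 apart (highest shuffle 0.233) argues against co-regulation confined to single bins. It cannot tell co-regulation over wider regions from copy number, because the shuffles remove all order of genes. The medians of weakly and strongly expressed genes were correlated across bins (0.633, highest shuffle 0.230), which copy-number differences between the cells may give, but their sizes were close in some segments, such as -0.31 and -0.33 on chromosome 1 from 9.85 to 21.9 Mb, and apart in others, such as 0.29 and 0.72 on 19p from 0.301 to 18.2 Mb and -0.68 and -0.14 on chromosome 17 from 76.4 to 82.8 Mb. Copy number is therefore an open hypothesis from the same data; karyotypes were not analysed here, and whether such differences would stem from the knockout or from the choice of cells was not tested.

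Genes beyond PIM3 on 22q were lower by a median of -0.56 against length-matched lists. A shift of the whole of chromosome 22 is argued against by its remaining 188 genes, at -0.0357 (percentile 21.1). Loss of the chromosome end beyond the site cleaved by Cas9 may contribute, but of 595 windows of 16 genes over the genome, 3 on other chromosomes had medians as low, and the nearest 16 genes on the centromere side were also lower (-0.37, percentile 1.43). Such a loss cannot be told apart from the regional shifts seen elsewhere, because DNA copy number was not analysed here.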
